A study of Oryza sativa with 122 samples.

How the data were processed

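RNA was extracted from root tips and leaves of field-grown rice, equal amounts from 3 plants were pooled for each library, and strand-marking libraries of polyadenylated RNA were prepared, per the labels' protocols. The deposited values are raw counts per gene identifier, 1 file for each line and tissue. STAR, featureCounts 1.6.4 and the genome build IRGSP-1.0 are named per the submitters' processing notes. The version of STAR, the gene annotation release, and the settings for strand, for reads that map to several places and for reads that overlap 2 genes are not given in the sources used here. Counts of near-identical gene copies, overlapping genes and antisense genes are therefore uncertain. All lines were set against 1 build, which is based on the cultivar Nipponbare (WRC01), so a line whose sequence differs more can lose reads.

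Each file lists the same 55986 identifiers, of which 55801 name a chromosome and 185 do not, and the latter had 0 counts in every library. No identifier matched the 39387 genes of the reference table used here. For this reason 12 lists of known genes (136 members) and 20 lists defined by words in gene descriptions, all fixed before the data were examined, could not be applied, and no gene is named. The chromosome was read from the identifier. The place of a gene is its order in the files along the chromosome, and 240 identifiers stood out of number order there. No 2 files held identical counts.

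Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9. Root tip and leaf were compared with edgeR's quasi-likelihood F-test on counts, with TMM scaling and the default expression filter, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 fold change of at least 1. Line effects were tested with an F-test of the 60 line terms in a model of tissue and line, over genes with a CPM of at least 1 in at least 10 libraries of each tissue. The shared part of the variance is the intraclass correlation of the 2 libraries of a line after centring each tissue. The SE of a log2 fold change is its absolute value divided by the square root of F, so it is derived from the test statistic and not estimated separately. Log2 CPM used TMM factors and a prior count of 2. CPM of the named tissue and line genes, and the minimums by which they were named, are TMM-scaled and use the total over the tested genes, and the other CPM, those in expression filters included, use the library total. Both tests were run on simulated counts with the real library sizes and a dispersion of 0.15. The tissue test called 99 of 100 genes simulated with a log2 change of 1.5, 97 of 97 with a change of 3 and 0 of 21455 unchanged genes, of 21652 genes in that simulation. The line test called 95 of 99 genes with a between-line SD of 0.5, 100 of 100 with an SD of 1 and 13 of 15274 genes without a line effect, of 15473 genes. In both simulations few genes changed and all genes had the same dispersion, so they do not test the scaling where most genes differ. On the real counts, 1 random pairing of leaf libraries with lines gave 186 edgeR line calls.

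Libraries were grouped by the tissue in the labels. The labels also give each library's line, which pairs 1 root tip with 1 leaf library. The pairing was checked on deviations from the tissue means, and all 61 pairs correlated by more than 0.1, with a median of 0.413 and a lowest value of 0.193. The tissue comparison was fitted without the line as a block and again with it. The labels give no sequencing batch, harvest day or plot, so none could be entered in a model.

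Spread between lines was compared through the SD of log2 CPM over genes with at least 1 CPM in at least 50 libraries of each tissue, with 100 swaps of the tissues within lines. Similarity used Pearson correlations across the same genes and a Mantel test with permuted line labels. Chromosomes were tested with 10000 circular shifts of the calls along the gene order, Benjamini-Hochberg adjusted over 12 chromosomes for each of 5 sets of calls, and neighbours with 1000 shuffles. The near-isogenic line and the silent genes were described without a test, as 1 library per line and tissue gives no replicate. Genes were named by a rule fixed before the data were examined: the largest fold in each direction among called genes with at least 50 CPM in the higher tissue and 1 direction in all lines, the largest F among genes with at least 10 CPM in a tissue, the largest mean difference for the near-isogenic line, and the highest median among genes silent in at least 5 lines. Of these, at most 2 identifiers in each direction are printed, since the files do not pair them with names.

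Depth limits low levels. A count of 0 allows 3 counts of the library total, between 0.0558 and 0.180 CPM, and intervals for single libraries are exact 95% Poisson intervals. Alternatives covered scaling (RLE, upper quartile), filters, DESeq2, limma-voom, a test against 2-fold, the line as a block, other fold minimums, subsets of lines, thinned libraries and other measures of spread and correlation. After the data were examined, 7 lines with foreign transcripts in their leaf libraries were left out as a further alternative.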

Results

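Gene expression was measured by RNA sequencing in root tips and leaves of 61 lines of rice (Oryza sativa) grown together in an upland field, that is, in unflooded soil. Of these lines, 57 came from the NARO World Rice Core Collection (WRC), a panel assembled to cover much of the diversity of cultivated rice. The other 4 were IR64, a lowland cultivar with shallow roots, Kinandang Patong (KP), an upland cultivar with deep roots, a near-isogenic line of IR64 named for DRO1 (Dro1-NIL), and Koshihikari (Kos). DRO1 is a gene on chromosome 9 that controls the angle at which roots grow. Each line gave 1 root tip library and 1 leaf library, and each library was a pool of RNA from 3 plants. The labels give no root measurement or subspecies for any line, so lines were compared only by name. The p-values of the tissue comparison rest on the spread between lines, since no line was sequenced more than 1 time in a tissue. Those of the line effects rest on how far root tip and leaf of a line depart from a shared difference. Permutation p-values rest on what was shuffled, shifted or swapped.

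The libraries were deep. Root tip libraries held 31588001 ± 5994429 counted reads (SD, n = 61), from 21496504 to 48596863, and leaf libraries held 32822468 ± 6885049 (SD, n = 61), from 16711032 to 53722730. Counts were found for 25185 ± 586 genes in root tip and 25194 ± 742 genes in leaf (SD, n = 61 each). A few genes dominated the leaf. The 10 most abundant genes took 16.2% ± 1.40 of the counts in leaf and 3.63% ± 0.354 in root tip (SD, n = 61 each), and the single most abundant gene took 3.80% ± 0.571 in leaf and 0.596% ± 0.119 in root tip. A count of 0 allowed an abundance of up to 0.0558 CPM (counts divided by the library total, per 1000000) in the deepest library and up to 0.180 CPM in the shallowest, counting error only. The files pair gene identifiers with no names, so genes are given below by identifier, chromosome and order along the chromosome.

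Root tip and leaf differed in most of the transcriptome. Of 21717 genes tested, 7572 were at least 2-fold higher in root tip and 7602 were at least 2-fold higher in leaf, together 69.9% of the genes. The differences were often large, with 2578 genes at least 16-fold higher in root tip and 3131 at least 16-fold higher in leaf. They also held across the diversity of the panel: 6212 of the root tip genes (82.0%) and 5901 of the leaf genes (77.6%) had the same direction in all 61 lines. The calls came from edgeR's quasi-likelihood F-test with Benjamini-Hochberg adjusted p under 0.05 and a 2-fold minimum. Without the fold minimum, 20499 genes (94.4%) passed the adjusted p.

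Among the genes that reached 50 CPM after TMM (trimmed mean of M-values) scaling and kept 1 direction in all lines, the largest differences were nearly on and off. The CPM of these named genes divide each count by the library's total over the tested genes times its TMM factor, which had a mean of 1.44 in root tip and 0.696 in leaf, so they are on another scale than CPM of the library total. LOC_Os04g24319, on chromosome 4, had 57.6 ± 43.6 TMM-scaled CPM in root tip and 0.0651 ± 0.196 in leaf (SD, n = 61 each), with 0 counts in 51 leaf libraries. Its log2 fold change was 9.69 ± 0.28 (SE, edgeR adjusted p = 3.89e-92). LOC_Os11g02350, on chromosome 11, had 117 ± 59.4 TMM-scaled CPM in root tip and 0.157 ± 0.506 in leaf (SD, n = 61 each), a log2 fold change of 9.65 ± 0.27 (SE, edgeR adjusted p = 8.34e-82). In the other direction, LOC_Os12g33130, on chromosome 12, had 316 ± 333 TMM-scaled CPM in leaf and 0.0164 ± 0.0201 in root tip (SD, n = 61 each), a log2 fold change of -13.92 ± 0.41 (SE, edgeR adjusted p = 2.3e-78). LOC_Os08g07080, on chromosome 8, had 201 ± 421 TMM-scaled CPM in leaf and 0.00928 ± 0.0212 in root tip (SD, n = 61 each), with 0 counts in 47 root tip libraries. Its log2 fold change was -13.94 ± 0.76 (SE, edgeR adjusted p = 1.96e-35), and its leaf level varied between lines by more than its mean.

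**Figure D1:**
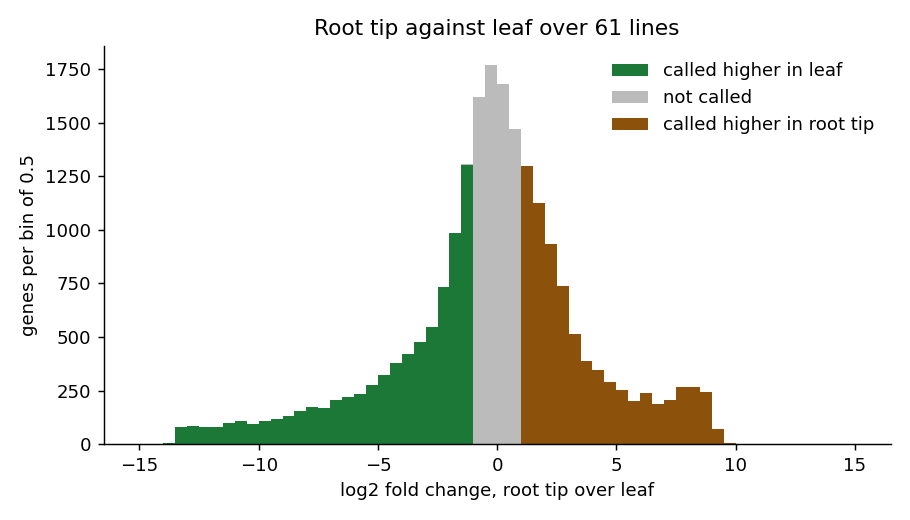
Histogram of the log2 fold change of root tip over leaf for 21717 tested genes, in bins of 0.5, with genes called higher in leaf (7602), higher in root tip (7572) or neither. The leaf side reaches -13.94 and the root tip side 9.69 among the named genes.

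The named root tip genes had smaller folds than the named leaf genes, and their folds rose when a few leaf libraries were left out. Among 95 genes with a root tip mean of at least 100 CPM and a leaf median under 0.1 CPM, the leaf libraries of 6 lines held transcripts at more than 0.5% of the root tip level. The median over the 95 genes was 1.73% of the root tip mean in WRC49, 1.44% in WRC48, 0.969% in WRC50, 0.758% in WRC45, 0.591% in Kos and 0.578% in WRC47. The next library, WRC06, stood at 0.223%, and the one after it at 0.095%. Without these 6 lines and WRC25, described further on, the log2 fold change of LOC_Os04g24319 was 12.32 and that of LOC_Os11g02350 was 11.54, while 7900 genes were higher in root tip and 7271 higher in leaf. This set of lines was left out after the data were examined.

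**Figure D2:**
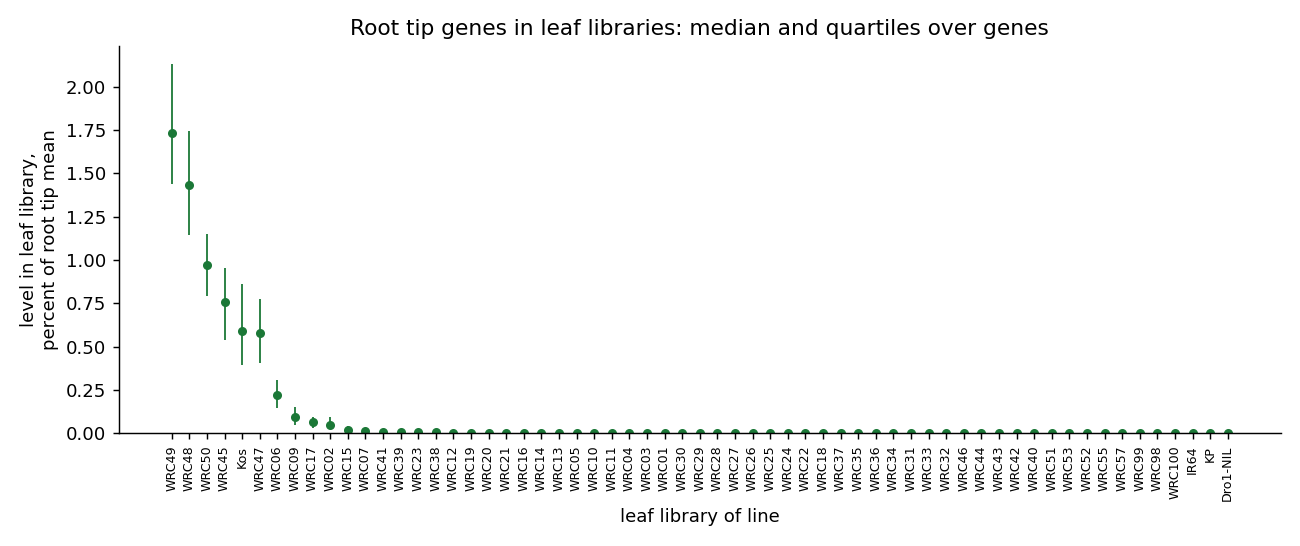
Level of 95 root tip genes in each of the 61 leaf libraries, as a percent of the mean over root tip libraries, with points for the median over genes and bars for the quartiles. The first 6 libraries lie between 0.578% and 1.73%, and the seventh lies at 0.223%.

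Genes higher in one tissue were spread over the 12 chromosomes. The share of tested genes that was higher in root tip ran from 32.9% on chromosome 9 to 36.9% on chromosome 5. The share higher in leaf ran from 32.3% on chromosome 12 to 37.1% on chromosome 1. No chromosome passed a two-sided permutation test that shifted the calls along the gene order. The lowest adjusted p was 0.6245 for root tip and 0.6185 for leaf over 12 chromosomes each. Short shifts leave most calls of a chromosome on it, which limits how small p can be. Neighbouring genes shared their direction more often than in shuffled calls. Both members of 2985 pairs of neighbouring tested genes were higher in root tip, against a mean of 2639 in 1000 shuffles of the calls, and both members of 3017 pairs were higher in leaf, against 2660. Each permutation p was 0.001, the smallest that 1000 shuffles can give.

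Lines differed from each other in ways that both tissues shared. Of 15693 genes with at least 1 CPM in at least 10 libraries of each tissue, 5964 (38%) had a line effect common to root tip and leaf. In these genes the shared part took a median of 0.48 of the variance between lines within a tissue, with quartiles of 0.341 and 0.741, against 0.0566 in the genes that were not called. The calls and the shared part rest on nearly the same ratio, so a gap between called and other genes follows from the calling. In the called genes, the lines with the highest and lowest mean level lay a median of 1.85 log2 units apart. In 1777 of these genes they lay at least 4 log2 units apart. The test was edgeR's quasi-likelihood F-test of all line terms in a model with tissue and line, at a Benjamini-Hochberg adjusted p under 0.05. A line effect holds whatever the 2 libraries of a line share, including plot, handling and how well its reads map to the 1 reference genome.

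In the strongest line effects, a gene had counts in both tissues of some lines and next to none in the others. A missing gene, a silent gene or a sequence too different to map to the 1 reference genome would look the same here. LOC_Os08g02904, on chromosome 8, was under 1 TMM-scaled CPM in both tissues of 49 lines and over 1 in both tissues of the other 12 lines (F = 197.6, edgeR adjusted p = 1.61e-33). Where it was present it ranged from 37.8 TMM-scaled CPM in WRC03 to 55.02 in WRC44 in root tip, and from 60.8 in WRC48 to 110.0 in WRC43 in leaf. LOC_Os11g34820, on chromosome 11, was under 1 TMM-scaled CPM in both tissues of 42 lines and over 1 in both tissues of the other 19 lines (F = 188.5, edgeR adjusted p = 1.31e-30), reaching 29.4 TMM-scaled CPM in root tip and 84.9 in leaf. No line had either gene in 1 tissue alone. In 1286 called genes the shared part took at least 0.8 of the variance.

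These stable differences often lay next to each other. Both members of 359 pairs of neighbouring tested genes belonged to the set with a shared part of at least 0.8, against a mean of 105 in 1000 shuffles, a ratio of 3.41 (permutation p = 0.001, the smallest that 1000 shuffles can give). Over all genes with a line effect, a set of 38% of the tested genes instead of 8.19%, the ratio was 1.14. Line effects were called for 54.7% of the tested genes on chromosome 11 and 49.8% on chromosome 12, against 33.4% on chromosome 3. No chromosome passed a two-sided permutation test that shifted the calls along the gene order. Chromosome 11 had an unadjusted p of 0.0428 and an adjusted p of 0.3978 over 12 chromosomes. Short shifts leave most calls of a chromosome on it, which keeps p from being small. The test can therefore not exclude that these chromosomes stand apart.

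Lines differed more in leaf than in root tip. Over 12397 genes expressed in both tissues, the SD between lines of log2 CPM had a median of 0.221 in root tip and 0.318 in leaf. The median of the log2 ratio of root tip SD over leaf SD was -0.42, and the SD was larger in root tip for only 25.5% of these genes. In 100 random swaps of the 2 tissues within lines, the median lay no farther from 0 than 0.154 (two-sided permutation p = 0.0099, the smallest that 100 swaps can give). With 1 library per line and tissue, the spread holds handling and sampling as well as the differences between lines.

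Lines that resembled each other in root tip also did so in leaf. After centring each tissue on its mean, the pairwise correlations of lines in root tip and in leaf had a Mantel r of 0.721 (permutation p = 0.0001, the smallest that the permutations can give). The highest r of the permutations was 0.173. With only the 2000 genes of highest mean, r was 0.36 (permutation p = 0.0001). The median correlation of a root tip library with the leaf library of its own line was 0.413, from 0.193 to 0.652, and with the leaf library of another line it was -0.021, computed across genes, which are not independent replicates. The own leaf library was the best match for 58 of 61 root tip libraries. The root tips of WRC12, WRC99 and IR64 instead matched the leaves of WRC11, WRC17 and Dro1-NIL best.

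IR64 and Dro1-NIL had the highest mean correlation of all pairs, with 0.799 in root tip and 0.803 in leaf. Next came WRC17 and WRC99, with 0.880 in root tip and 0.680 in leaf. WRC01, the cultivar Nipponbare on which the reference genome is based, and Koshihikari, both Japanese temperate cultivars, stood at 0.702 in root tip and 0.764 in leaf. WRC43 was close to both, with 0.728 and 0.704 to Koshihikari and 0.667 and 0.719 to WRC01. KP was closest to WRC47 in both tissues, at 0.517 in root tip and 0.707 in leaf. In all, 25 of 61 lines had the same nearest line in both tissues, where 1.02 would arise by chance.

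**Figure D3:**
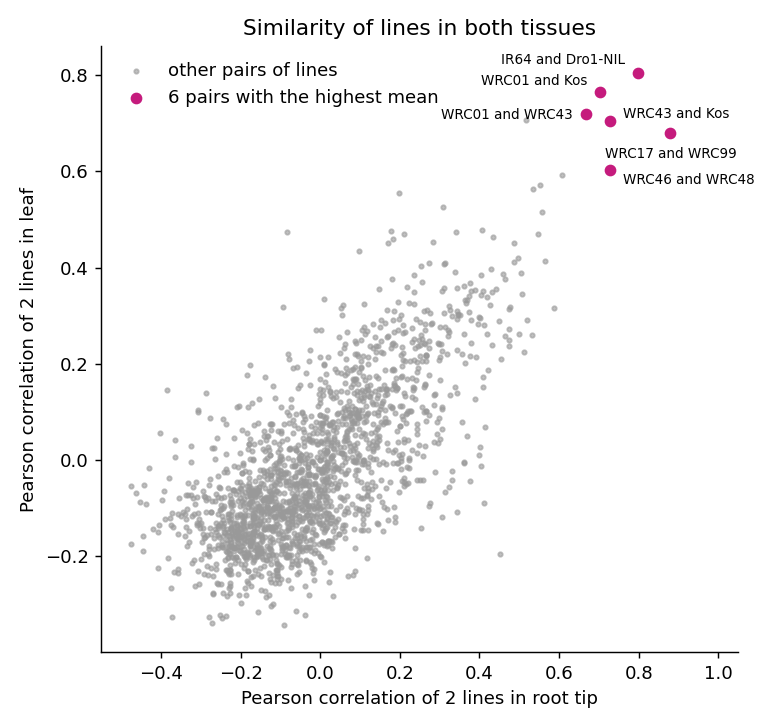
Pearson correlation of each pair of lines in root tip (horizontal axis) and in leaf (vertical axis), computed across 12397 genes after centring each tissue. The 6 pairs with the highest mean are coloured and named, and IR64 with Dro1-NIL lies at 0.799 and 0.803.

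The near-isogenic line was compared with IR64, to which it is near-isogenic, and with KP. With 1 library per line and tissue there was no test. A gene was counted when the 2 lines differed at least 4-fold in the same direction in both tissues and the higher library of each tissue had at least 20 counts. By this rule 19 genes differed, 18 higher and 1 lower in Dro1-NIL, and all 19 differed from IR64 in the same direction in KP. Both differences use the same IR64 libraries, and a gene without counts in IR64 cannot be lower in KP. The shared direction is therefore no test of KP origin. Only WRC17 and WRC99 differed in fewer genes (5) among all pairs of lines, where the median was 648.5 and the highest was 1047. KP and IR64 differed in 860 genes.

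The 19 genes lay on few chromosomes. On chromosome 9 there were 6 genes, 31.6% of the total, where the highest share in any other pair of lines was 10.2%. They lay between gene 2274 and gene 2825 of the 3407 gene identifiers along the chromosome. Chromosome 1 held 10 genes, 52.6%, where the highest share in any other pair was 17.9%. Of the remaining 3 genes, 2 lay on chromosome 12 and 1 on chromosome 3. At a minimum of 2-fold there were 37 genes, of which 15 lay on chromosome 9, all within the same interval, and 13 on chromosome 1. The other 9 lay elsewhere, and 30 of the 37 differed from IR64 in the same direction in KP. At a log2 difference of at least 3 there were 16 genes, 4 on chromosome 9, 10 on chromosome 1 and 2 elsewhere. With at least 100 counts in the higher library of each tissue, only 7 genes remained. Of these, 2 lay on chromosome 9, 2 on chromosome 1 and 3 elsewhere.

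On chromosome 9 the near-isogenic line was within 2-fold of KP in both tissues for 5 of the 6 genes, and for 9 of the 15 genes found at a minimum of 2-fold. The exception among the 6, LOC_Os09g26530, had 2.068 CPM in the root tip of Dro1-NIL and 0.631 CPM in that of KP. Among the others, LOC_Os09g27820 had 2.272 CPM in the leaf of Dro1-NIL and 0.142 CPM in that of KP. These exceptions were chosen after their values were seen. LOC_Os09g26554 had 0 counts in both IR64 libraries, which allows up to 0.113 CPM in root tip and 0.111 CPM in leaf. It had 51.1 CPM in the root tip of Dro1-NIL (95% Poisson interval 48.5 to 53.7) and 57.2 CPM in that of KP (54.9 to 59.6), and 5.64 CPM (4.8 to 6.59) against 8.29 CPM (7.26 to 9.42) in leaf. LOC_Os09g32860 went the other way, with 1.69 CPM (1.23 to 2.26) in the root tip of IR64 and 0 counts in the root tips of Dro1-NIL and KP. On chromosome 1 the level lay between those of IR64 and KP in both tissues for 9 of the 10 genes, and for 10 of the 13 genes found at a minimum of 2-fold. The exception among the 10, LOC_Os01g53830, also named after its values were seen, had 5.29 CPM in the root tip of Dro1-NIL and 4.669 CPM in that of KP. LOC_Os01g71630 had 0.188 CPM (0.061 to 0.438) in the root tip of IR64, 47.7 CPM (45.2 to 50.3) in that of Dro1-NIL and 326 CPM (321 to 332) in that of KP. In leaf it had 0 counts in IR64, 53 CPM (50.3 to 55.7) in Dro1-NIL and 313 CPM (307 to 320) in KP. The intervals cover counting error only.

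**Figure D4:**
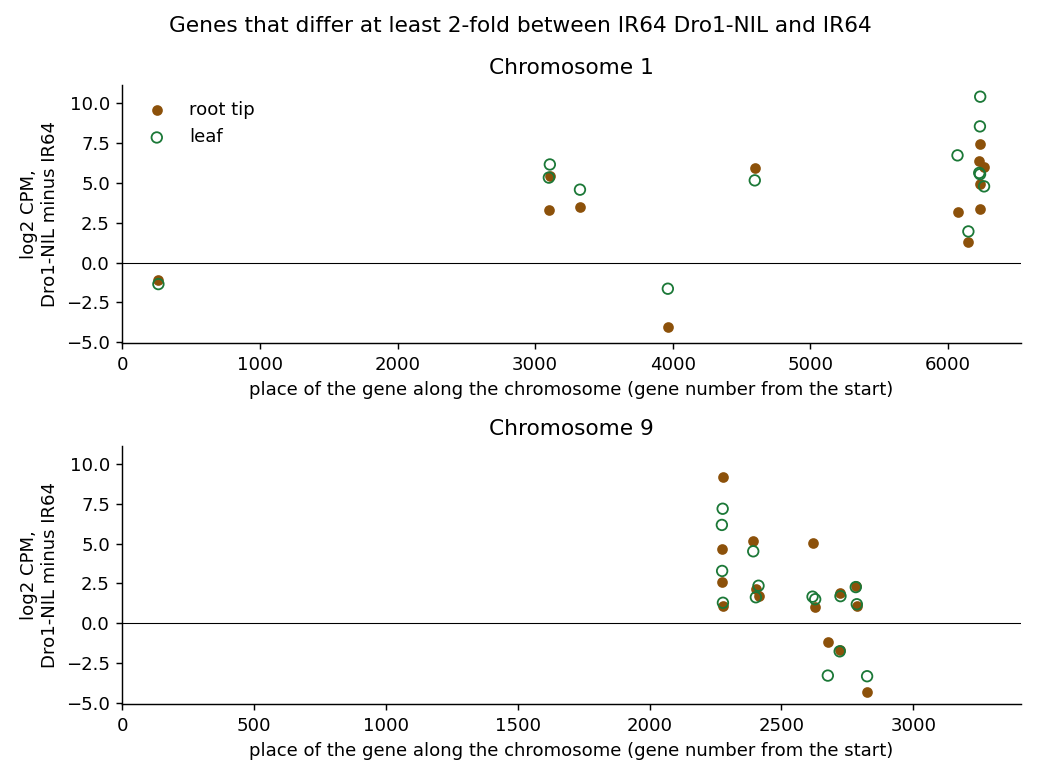
Difference in log2 CPM between Dro1-NIL and IR64 (vertical axis) for the 13 genes on chromosome 1 and the 15 genes on chromosome 9 that differed at least 2-fold in both tissues, by order of the gene along the chromosome (horizontal axis). Filled points are root tip and open points are leaf, and the chromosome 9 genes all lie between gene 2274 and gene 2825.

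Differences were far more common when each tissue was taken by itself. In root tip 339 genes differed at least 4-fold between Dro1-NIL and IR64, of which 295 were lower in Dro1-NIL, and in leaf 186 genes differed, of which 157 were higher in Dro1-NIL. They were less concentrated than the 19 genes. In root tip 6.49% lay on chromosome 9 and 23.6% on chromosome 1, and in leaf 18.28% and 24.19%. In KP, 330 of the 339 genes and 134 of the 186 differed from IR64 in the same direction as in Dro1-NIL, so most of these root tip genes put IR64 on 1 side and both other lines on the other. The genes were chosen for differing from the same IR64 library, so some agreement arises from this choice alone. Of the 295 genes, 183 were among those tested between the tissues, and 136 of these (74.3%) were called higher in leaf over all lines, against 35% of all tested genes. At least 16-fold higher in leaf were 89 (48.6%), against 14.4% of all tested genes. Such differences have no replicate to set them against.

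Every line had genes that most lines express and that it lacked. A gene was counted as silent in a library when it had 0 counts there although its median in that tissue was at least 5 CPM and at least 20 counts would be expected. By this rule 434 genes were silent in at least 1 root tip library and 300 in at least 1 leaf library, with a median of 54 genes per line in root tip and 31 in leaf. Among 9084 genes at 5 CPM or more in both tissues, 774 of 1352 silent calls in root tip (57.3%) recurred in the leaf library of the same line. Matched to the leaf library of another line, 230 recurred on average and at most 388 over 60 rotations of the lines. These shared calls involved 139 genes, of which 38 were silent in both tissues of 1 line and 58 in both tissues of at least 5 lines.

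Among the genes silent in both tissues of at least 5 lines, LOC_Os03g22720 on chromosome 3 had the highest root tip median, 75.6 CPM, with 8.68 CPM in leaf, where other such genes were higher, and was silent in both tissues of 5 lines. LOC_Os04g40190, on chromosome 4, had a median of 65.2 CPM in root tip and 24.03 CPM in leaf. It was silent in the root tips of 13 lines and the leaves of 13 lines, and in both tissues of 5 lines. Silent genes also sat side by side. Of the 139 genes, both members of 15 pairs of neighbours were silent in some line, against a mean of 2.1 in 1000 shuffles (permutation p = 0.001, the smallest that 1000 shuffles can give).

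The number of silent genes differed between lines. Koshihikari had the fewest in root tip, 9, followed by WRC20 with 17, WRC46 with 21, WRC43 with 24 and WRC01 with 30. WRC98 had the most in both tissues, 74 in root tip and 65 in leaf. WRC47 and WRC25 had only 7 silent genes each in leaf, against 35 and 57 in root tip. Of the genes with a median of at least 5 CPM in both tissues that were silent in a line's root tip, its leaf library had counts for 16 of 16 in WRC47, 30 of 31 in WRC49, 24 of 30 in WRC50 and 20 of 25 in WRC25. These genes stood at a median of 1.147% of the usual leaf level in WRC47, 3.567% in WRC49, 0.914% in WRC50 and 10.01% in WRC25 (quartiles 2.9% and 13.8%). Reads of all lines were mapped to 1 reference genome, so 0 counts can come from a missing gene, from a silent gene or from a sequence too different to map.

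**Figure D5:**
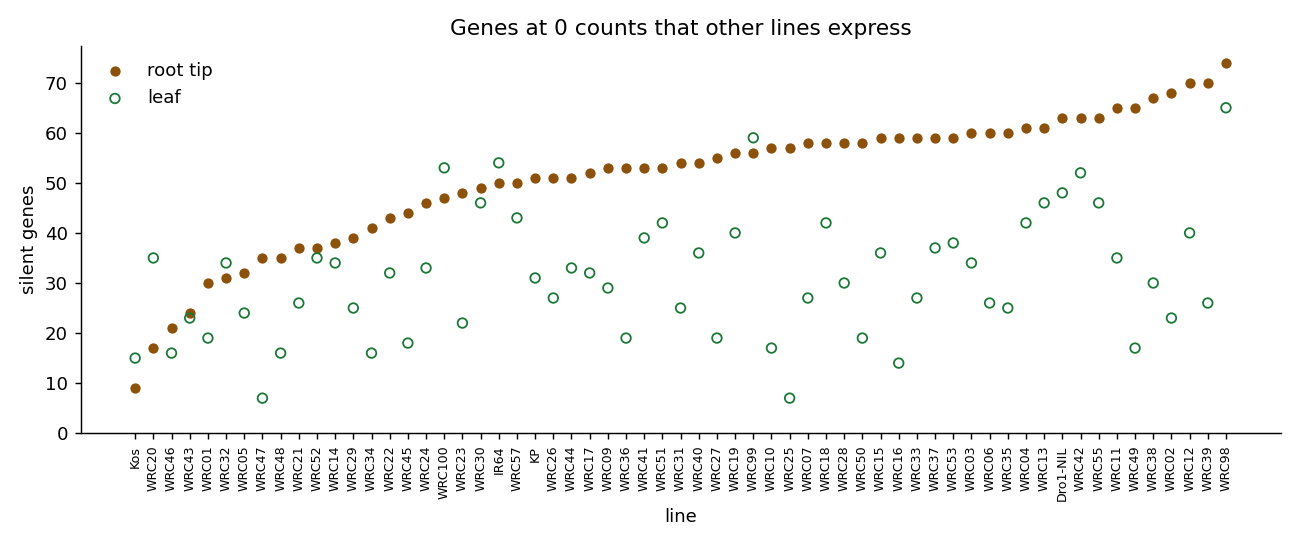
Number of silent genes in the root tip (filled) and leaf (open) library of each of the 61 lines, in order of the root tip number. Root tip numbers run from 9 in Kos to 74 in WRC98.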

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

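Leaving out the 7 lines (WRC25, WRC45, WRC47, WRC48, WRC49, WRC50 and Kos), or for similarity the 2 lines farthest from the median in root tip, was chosen after the data were examined, and the other settings before. For Dro1-NIL against IR64, 18 genes were higher and 1 lower, but in root tip alone 44 were higher and 295 lower, 339 in all. Of these, 330 differed from IR64 in the same direction in KP, and both comparisons share the IR64 root tip library. The reversal can therefore not be assigned to Dro1-NIL, and its cause was not tested. No other result reversed under the settings run for it. The tissue calls stayed within 1.5 times under 12 of the 13 settings for leaf and under all 13 for root tip, including the line as a replicate block (7694 higher in root tip, 7567 in leaf), which kept 7525 and 7465 of the calls. With no filter on low counts, 14255 genes were higher in leaf because 47292 genes were tested. Upper-quartile scaling moved the median of all genes by 0.31 log2 units and gave 8487 root tip and 6737 leaf calls. The 4 named tissue genes kept their call wherever they were tested, although limma-voom put LOC_Os08g07080 at -10.57. Line effects numbered 3112 where only genes with 5 CPM in 31 libraries of each tissue were tested, 9084 in all, and 186 when leaf libraries were paired with random lines, where both named genes lost their call (adjusted p 0.538 and 0.611). They stayed between 5533 and 6751 under the other 5 settings. For Dro1-NIL against IR64, 37 genes differed at 2-fold, 7 with 100 counts in the higher library and 186 in leaf alone, and the cause was not tested. With a median of at least 20 CPM, 140 genes were silent in root tip, 71 in leaf and 23 in both tissues of a line, from fewer genes. Spread and similarity kept their direction and their side of the threshold in all settings (median log2 ratio -0.46 to -0.39, Mantel r 0.36 to 0.744). Settings for gene lists were not run, as no list could be matched. Depth limits the silent genes to those with 20 expected counts.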

Other observations

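WRC17 and WRC99 differed in the fewest genes of all pairs by the rule used for the near-isogenic line. There were 5 genes, on 4 chromosomes, of which 4 were higher in WRC99 and 1 was higher in WRC17. The rule counts only differences found in both tissues. By correlation the pair ranked 1 of all pairs in root tip and 6 in leaf. LOC_Os03g08330, on chromosome 3, had 14 counts in the root tip of WRC17 and 103 in that of WRC99, with 60 and 2638 in leaf. LOC_Os04g21130, on chromosome 4, had 55 and 4 counts in root tip and 71 and 0 in leaf. These 2 genes were chosen after their values were seen. After this pair and IR64 with Dro1-NIL (19 genes), the fewest differences were between WRC01 and Koshihikari, 84 genes, and WRC43 and Koshihikari, 113.

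The tests in this part were chosen after the results they bear on were seen, except for the random pairing in edgeR, which was chosen before the data were examined. The test on root tip genes absent from a line's own root tip, below, had its bounds set before its result was seen. For the tissue calls, only the real split, 1 of 60 splits of the libraries, reached 15174 calls, and the highest other split gave 130. The other splits were random and mixed both tissues in each group, which widens the spread within groups. This outcome was therefore foreseeable and adds little to the F-test. For line effects, 100 pairings of root tip with leaf libraries were compared with limma-voom, and only the real 1 reached 6751 calls. The highest other pairing gave 2812 and the median 2345, so limma-voom called many genes whichever lines were paired, and why was not tested. edgeR gave 186 calls for the 1 random pairing run.

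Transcripts of 95 root tip genes in the leaf libraries of WRC45, WRC47, WRC48, WRC49, WRC50 and Koshihikari were weighed against explanations. Root tip RNA or reads in the leaf library would put all genes in 1 proportion, and between 83.2% and 93.7% of the genes lay within 2-fold of their library's median, consistent with this. Whether the line's own root tip was the only source of these transcripts stays open. These libraries did hold transcripts of genes with 0 counts in the own root tip and a median over lines of at least 5 CPM in both tissues. They were found for 30 of 31 such genes in WRC49 (median 3.567% of the usual leaf level, quartiles 1.515% and 5.865%) and 16 of 16 in WRC47 (1.147%, quartiles 0.75% and 1.705%). In WRC50 it was 24 of 30 (0.914%, quartiles 0.396% and 2.02%) and in WRC45 13 of 17 (1.325%, quartiles 0.343% and 2.68%). In WRC48 it was 11 of 16 (0.921%, quartiles 0% and 1.716%) and in Koshihikari 1 of 2, while the median library outside the 6 had a median of 0. The own root tip library shows no source for these transcripts, but leaves express such genes, and WRC25 has them without root tip transcripts, so they do not tell where the root tip transcripts came from. Root tip genes with 0 counts in that line's own root tip library would then be absent, and 17 of 26 such values, from 11 genes, were above 0 in these leaf libraries, against 28 of 290 in the 55 others, WRC25 included. Their median was 53.4% of the level expected from the library's share of root tip transcripts, but the quartiles, 0% and 195.9%, were too wide to decide, and no batch is given. Among these genes, LOC_Os11g39310 had 1284 counts in the leaf of WRC47 and 560 in that of WRC49. Outside the 6 libraries it ranged from 0 in WRC26 to 1852 in WRC22, so in several lines it was not restricted to root tip. The design gives no biological explanation, and none was tested.

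Many genes on chromosome 1 had a level in Dro1-NIL between those of IR64 and KP. Among genes with at least 5 CPM in KP and at most 2 counts in IR64, 13 of 27 on chromosome 1 exceeded 5% of the KP level in the root tip of Dro1-NIL (median 20.1%, quartiles 15.2% and 23.8%), all in runs from gene 3100 to 4333 and from 6229 to 6264. RNA of KP mixed into the libraries is argued against by the chromosomes other than 1 and 9, where at most 2.35% of the genes exceeded 5% in a tissue. Segments of KP origin carried by part of the pooled plants go with the place of the genes in leaf, but not readily with their level there, given below. Of the 11 leaf genes inside the root tip runs, 5 had helped to define them, and the other 6 all exceeded 5%, against 1 of 28 outside. These 6 include LOC_Os01g39680, LOC_Os01g71620, LOC_Os01g71624 and LOC_Os01g71630, which were already counted above as higher than in IR64 in both tissues. For them, leaf is no independent check. No p is given, since linked genes are not independent. Levels varied on chromosome 9 too: LOC_Os09g26554, LOC_Os09g29540 and LOC_Os09g29560, chosen after their values were seen, stood at 68.1%, 16.16% and 3.79% of KP in leaf. As a hypothesis, 1 plant of 3 would give 33.3% and 1 chromosome copy in 1 of 3 plants 16.7%. The latter is the smallest share, if plants contribute equally and each copy is expressed as in KP. The root tip median, 20.1%, lay between these values, but the leaf median, 9.1% (quartiles 8.3% and 21.2%), lay below both. No number of plants alone accounts for the leaf median, and why it was lower was not tested. The number of plants stays open.

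The leaf library of WRC25 had transcripts for 20 of 25 genes with 0 counts in its root tip library, at a median of 10.01% of the usual leaf level, while its median for the 95 root tip genes was 0. A leaf library of another line under this label is argued against, since its best match was its own root tip library (r = 0.402). Genes active near the usual level in the leaf of this line, and not in its root tip, are argued against too, since only 1 of the 25 genes reached 50% of that level. This bound cannot exclude weak activity in leaf. Whether RNA of 1 other line was present stays open. The best match of detected and undetected genes with 1 line, 22 of 25, was no better than in shuffles (permutation p = 0.2118) and was shared by 5 lines. Several lines as source stay open too. An off-type plant in the pool was not tested.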
